A study of Mus musculus with 6 samples.

How the data were processed

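Per the labels, LLC cells were grown in medium with serum and treated with DMSO or with 5 µM STM2457 for 46 h, total RNA was extracted with TRIzol, and libraries were made with a SMARTER mRNA-Seq kit. Per the submitters' processing notes, the tools included FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.1 from Subread, and DESeq2, with the GRCm38 genome build. The annotation used for counting, the alignment settings and the use of strand are not given in the sources used here. Samples were placed in their groups by the treatment in their labels, 3 per group, and every column of the table was matched to a sample by its name.

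The authors deposited a table of log2 values with 1 row per gene symbol and 1 column per library. It holds 55367 rows, of which 31229 are listed at 0 in all 6 libraries. The transform is not given in the sources used here. From the values, it has the form of a regularised log2 transform, in which each gene's log2 values are shrunken towards the mean of the libraries, more strongly at low counts. The fitted prior SD was 0.186 on the log2 scale, and at the highest counts 60.0% of a log2 difference is kept. Log2 differences of the deposited values therefore understate the change, most of all for low genes.

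The equations of that transform were inverted to recover the reads. A ridge penalty of 60.27, a dispersion of 1.898 over the mean plus 0.0111 and size factors from 0.995 to 1.01 were estimated from the values. For the 17546 genes with a mean under 500 reads, 98.3% of the recovered values were whole to within 0.05 reads, and the recovered values were rounded. Of these genes 10361 had a mean under 5 reads, and from 100 to under 500 reads 92.8% of the values were whole. Above a mean of 500 the error in reads grows and whole numbers no longer test the result. There 46.8% were whole from 500 to under 2000 reads and 16.9% from 2000. Many genes given in reads below, such as Neat1 and Tfrc, lie in that range. On simulated counts for STM2457 against DMSO (22750 genes, 16162 with a mean under 500), transformed by the same equations, the inversion gave back 100.00% of the values under that mean. The libraries held 17671485 to 17917198 reads in genes, so that 3 reads, the limit that a count of 0 allows, come to 0.167 to 0.170 CPM. That limit covers counting error only.

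The design fixed before the data were examined assumed counts and named a limma fit for the case of normalised values. As the table holds log2 values, limma was used, with no pseudocount because the values are already on a log scale. Genes with a mean deposited value of at least 3.32, the log2 of 10 reads, were tested: 12618 genes. Linear models with the group as the only term were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and robust priors, statmod 1.5.0), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A 2-fold change means a log2 difference of at least 1 in size. Folds and levels in the text come from the recovered reads: limma-voom fitted the folds, and normalised reads are recovered reads divided by the library's size factor. On simulated data for STM2457 against DMSO with 200 changed genes among 12636, limma on the transformed values called 95 of 100 genes changed by a log2 fold of 1 (median fitted size 0.50), 86 of 100 changed by 0.5 (0.26) and 12 of 12436 unchanged genes. Limma-voom on the recovered reads called 95, 84 and 13, with median fitted sizes of 1.01 and 0.50. Every simulated gene had a dispersion of 0.0005. Rates for genes that vary more between libraries, such as Trib3 in DMSO (2881 ± 689 normalised reads), were not tested.

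Before the data were examined, 39 gene lists were fixed on m6A machinery, interferon and nucleic acid sensing, antigen presentation, chemokines, checkpoint ligands, cell cycle, stress, metabolism, RNA processing and other cell types. Their symbols were matched to the table directly (971), through older symbols (5) or through RefSeq synonyms (23). The 35 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the lists, and also with an estimated correlation and with fry. Camera compares a list with the other genes. Fry's directional p tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

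By a rule fixed beforehand the text draws its genes from Mettl3 and the other m6A list members, the 10 genes with the largest rise and the 10 with the largest fall in the deposited values among genes that passed the test, had a mean log2 CPM of at least 2, did not overlap between groups and had a gene name rather than a clone, pseudogene or identifier, up to 4 members of smallest adjusted p from each list that passed camera or concerns immunity, and Cd274, Cxcl1, Cxcl5, Cxcl10, Ccl5, Ccl20, Cdkn1a, Myc, Actb and Gapdh. Tlr3, Eif2ak2, Adar, Ddx58 and Dhx58 were added after their values were seen. Eligible list members without a value of their own in the text are covered by the counts of their list. Coordinates, transcript models and gene classes come from the GENCODE M21 annotation of the same GRCm38 build, in which 98.3% of the tested symbols were found.

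Replicates were compared before averaging. The chi-square of recovered reads per degree of freedom was 1.52 to 4.62 within groups and 19.40 to 25.73 across groups, so no library repeats another within sampling noise. Alternatives fixed beforehand were upper-quartile centring, no filter on low values, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, an adjusted p under 0.01, and for lists the estimated correlation, fry and members not shared with another list. Limma-voom on the recovered reads, total-read scaling and counts of list members without DMSO replicate 2 were chosen after seeing the data. All 10 ways to split the 6 libraries into 2 groups of 3 were also fitted. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.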

Results

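RNA sequencing measured transcript levels in LLC cells, a mouse line from a Lewis lung carcinoma, cultured for 46 h with the solvent DMSO or with 5 µM STM2457. STM2457 is a small-molecule inhibitor of the catalytic activity of METTL3, the enzyme that writes N6-methyladenosine (m6A) on RNA. Each group held 3 libraries. The reads assigned to genes, recovered from the deposited values, numbered 17671485, 17676782 and 17679229 in DMSO replicates 1 to 3 and 17912066, 17917198 and 17877761 in STM2457 replicates 1 to 3. Of 24138 genes with at least 1 read, 12618 had a mean of at least 10 reads and were tested. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

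The comparison asks which transcripts differ between STM2457 and DMSO. After STM2457, 30 of 32 genes of the ATF4 stress response, 29 of 35 of glycolysis and hypoxia and 10 of 16 of myeloid cell attraction fell, and 27 of 38 genes of ribosome biogenesis and MYC targets rose. Each of these lists passed camera with its preset correlation, and none passed camera with an estimated correlation (adjusted p = 0.53). By fry, which does not compare a list with other genes, their adjusted p-values were 0.0038, 0.0038, 0.0028 and 0.0028 in that order. In all, fry passed 24 of 35 lists, so it does not set these apart. Those that passed included the m6A writer complex (fry adjusted p = 0.0013), interferon-gamma-induced genes (0.0015), SOCS genes (0.0028) and MHC class I presentation (0.004). Double-stranded RNA and DNA sensing (0.0081) and type I interferon-stimulated genes (0.035) passed too. T and NK cell attractants (0.27), checkpoint ligands (0.33) and NF-kappa-B targets (0.79) did not pass fry. Chac1, a glutathione-degrading enzyme induced by ATF4, fell from 1208 ± 206 to 249 ± 32.3 normalised reads (mean ± SD, n = 3). The pseudokinase gene Trib3 fell from 2881 ± 689 to 767 ± 10.1 and the nuclear long noncoding RNA Neat1 from 14723 ± 543 to 4485 ± 265 (SD, n = 3). Tfrc, which encodes the transferrin receptor that takes up iron, rose 2.66-fold, from 1407 ± 67.7 to 3745 ± 190 normalised reads (SD, n = 3). Mettl3 itself measured 537 ± 66.0 normalised reads in DMSO and 488 ± 32.5 after STM2457 (SD, n = 3), a difference within the spread of the DMSO libraries (limma adjusted p = 0.15).

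By limma on the deposited log2 values, 3868 genes were higher and 3240 lower after STM2457 at an adjusted p under 0.05. That split depended on the scaling: centring on the upper quartile gave 2819 higher and 4814 lower. Most changes were small: 79.5% of the called genes changed under 1.5-fold in the recovered reads. In 7795 of the tested genes, or 61.8%, all 3 libraries of 1 group lay above all 3 of the other, where chance gives 10%. The deposited values are shrunken towards the mean of the libraries, so that folds on their scale are too small. On that scale 0 genes rose and 3 fell at least 2-fold, both at an adjusted p and at an unadjusted p under 0.05, and without DMSO replicate 2 only 1 fell that far. The 3 were Chac1 (log2 difference -1.14, SE 0.09), Trib3 (-1.05, SE 0.12) and Neat1 (-1.01, SE 0.02). By limma-voom on the recovered reads, 72 genes rose and 362 fell at least 2-fold.

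**Figure D1:**
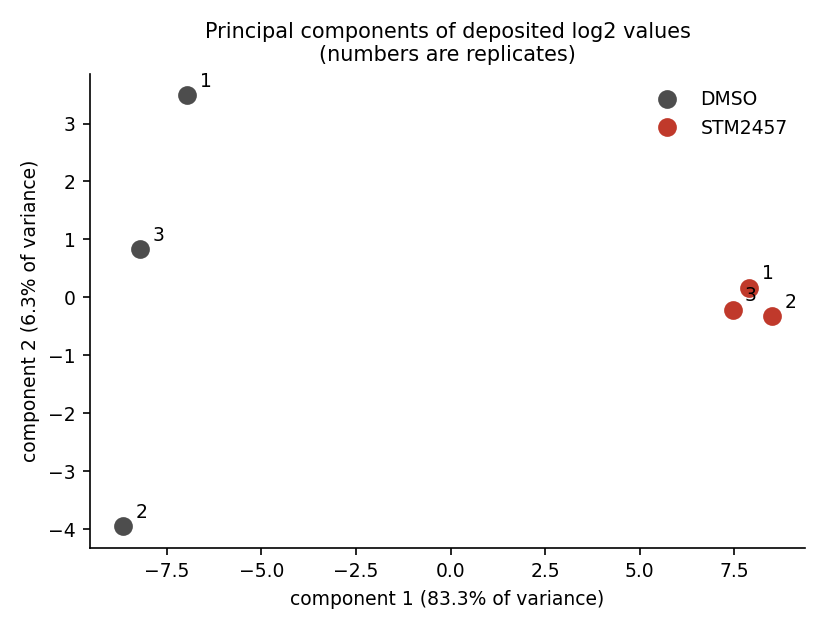
Principal components of the deposited log2 values of the tested genes, with component 1 (83.3% of the variance) on the x axis and component 2 (6.3%) on the y axis, 1 point per library, numbered by replicate and coloured by group. Component 1 separates the groups, and on component 2 DMSO replicate 2 (-3.95) lies farthest from DMSO replicate 1 (3.49).

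Ranked by the shrunken deposited values, the well-expressed genes with the largest rise besides Tfrc were Plekho1 (2.29-fold in the recovered reads), Chpf (2.04-fold), Tuba4a (2.00-fold), Arhgap31 (2.18-fold), Kti12 (2.02-fold), Tpst2 (2.00-fold), Umps (1.92-fold), Gnb1l (2.37-fold) and Gpatch4 (1.96-fold). Chpf encodes a chondroitin polymerizing factor, Tuba4a an alpha-tubulin and Umps an enzyme of pyrimidine synthesis. In the same ranking those with the largest fall, besides Chac1, Trib3 and Neat1, were Abi3bp (to 0.262 of the DMSO level), Gadd45a (0.299), Cxcl1 (0.377), Ero1l (0.393), Ly6c1 (0.386), Gpt2 (0.391) and Ddit4 (0.393). By the recovered reads the order differs, with Hspa1b (2.25-fold) and Rbm15 (2.05-fold) above Umps, and Cxcl5 (to 0.249), Ankrd37 (0.259) and Slc7a11 (0.356) below Cxcl1. Each of the 20 ranked genes passed the limma test, with adjusted p-values from 4.5e-20 for Neat1 to 0.0041 for Cxcl1. Ly6c1 has the close copy Ly6c2, with which reads may have been shared. In the annotation of the GRCm38 build, Tfrc lies on chromosome 16 from 32608920 to 32632794 on the plus strand, Chac1 on chromosome 2 from 119351229 to 119354381 on the plus strand, Trib3 on chromosome 2 from 152337422 to 152344032 on the minus strand, and Neat1 on chromosome 19 from 5824708 to 5845478 on the minus strand. Use of strand in counting is not given in the sources used here. The exons of Kti12, Tuba4a, Umps and Gadd45a overlap an annotated gene on the other strand, so their reads are uncertain to that extent. The same holds for Ndrg1, Ankrd37, Gapdh, Bysl, Cyp51, Il34, Irf1, Irf3, Pdia3, Cd274, Tgfb3, Tnfsf9, Cxcl10 and Cdkn1a, which are named below.

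**Figure D2:**
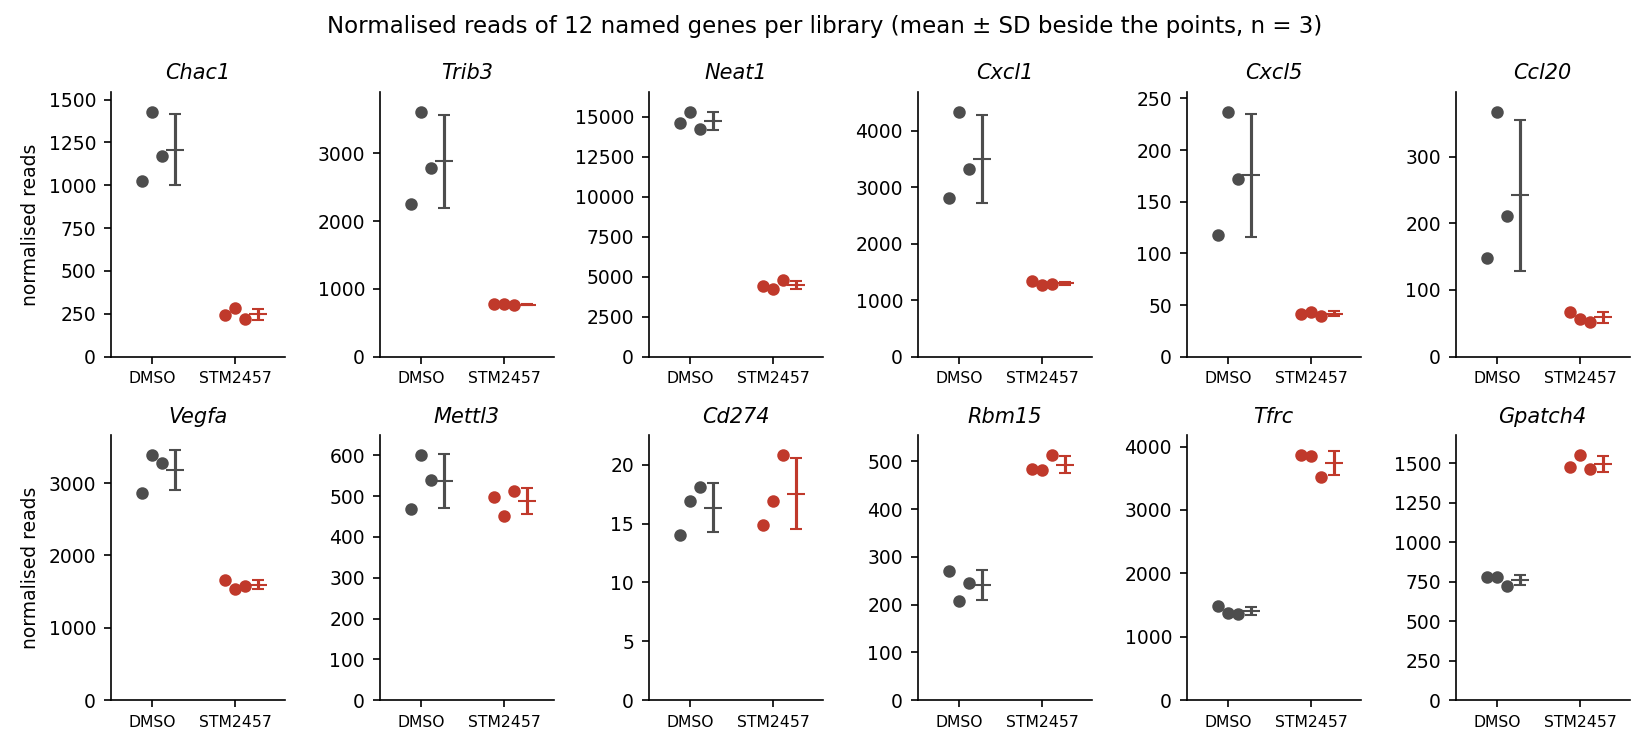
Normalised reads (y axis, linear from 0, recovered reads divided by the library's size factor) of 12 named genes, with 1 point per library in each group on the x axis and the mean ± SD (n = 3) beside the points. For Chac1, Trib3, Neat1, Cxcl1, Cxcl5, Ccl20 and Vegfa the STM2457 libraries lie below the DMSO libraries, for Rbm15, Tfrc and Gpatch4 above them, and for Mettl3 and Cd274 the groups overlap.

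Genes of the integrated stress response, which ATF4 switches on when amino acids are short or the endoplasmic reticulum is strained, were lower. Of 32 tested members, 30 fell and 0 rose, counted over all genes and also adjusted over the list alone. The median member fell to 0.635 of its DMSO level (camera adjusted p = 3.3e-17, and adjusted p = 0.53 with an estimated correlation). They included the cystine transporter Slc7a11, which fell from 759 ± 82.2 to 269 ± 24.2 normalised reads, the mitochondrial folate enzyme Mthfd2, from 5895 ± 424 to 3704 ± 43.4, the glycyl-tRNA synthetase gene Gars, from 10094 ± 592 to 6630 ± 107, and Ddit4, an inhibitor of mTORC1, from 2215 ± 61.8 to 871 ± 11.5 (SD, n = 3). In DMSO replicate 2, 31 of the 32 members lay above the mean of DMSO replicates 1 and 3, by a median of 0.13 on the log2 scale. Without that library 30 members fell.

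Glycolytic and hypoxia-induced genes also fell, 29 of 35 with 0 higher, and 30 adjusted over the list alone (camera adjusted p = 7.2e-13, and adjusted p = 0.53 with an estimated correlation). Vegfa, the vascular growth factor gene, fell from 3179 ± 274 to 1593 ± 61.1 normalised reads, Ndrg1 from 10052 ± 566 to 5177 ± 244, Ankrd37 from 213 ± 23.2 to 54.9 ± 5.41 and Bnip3l, a mitophagy receptor, from 4053 ± 174 to 2518 ± 140 (SD, n = 3). Gapdh, often used as a reference gene, fell to 0.819 of its DMSO level (limma adjusted p = 3.0e-07), and Actb rose 1.33-fold (7.5e-05). Members of this list lay lower in DMSO replicate 2 than in DMSO replicates 1 and 3 by a median log2 difference of -0.09, with 5 of 35 higher.

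Antioxidant genes under NRF2 fell in 15 of 25 cases and rose in 3, with 16 lower adjusted over the list alone (camera adjusted p = 3.0e-04, and adjusted p = 0.41 with an estimated correlation). Besides Slc7a11, which the ATF4 list also holds, the glutathione transferase gene Gstm1 fell to 0.551, the exporter gene Abcc1 to 0.678 and the transketolase gene Tkt to 0.703 of the DMSO level. Cytosolic ribosomal protein genes fell slightly, 25 of 47 with 1 higher, the same counts adjusted over the list alone (median 0.932 of the DMSO level, camera adjusted p = 9.5e-05, and adjusted p = 0.59 with an estimated correlation). Rpl3 fell to 0.745, Rpl14 to 0.827, Rps3 to 0.853 and Rps19 to 0.847 of the DMSO level. Ribosomal protein genes have many processed copies, with which reads may have been shared.

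Genes for ribosome biogenesis and MYC targets rose in 27 of 38 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 3.6e-05, and adjusted p = 0.53 with an estimated correlation). Besides Tfrc, the ribosomal RNA methyltransferase gene Nop2 rose 1.87-fold, the ribosome assembly factor gene Bysl 1.74-fold and Polr1b, for a subunit of RNA polymerase I, 1.65-fold. Myc, itself a member, fell from 12918 ± 1632 to 8660 ± 38.7 normalised reads (SD, n = 3, limma adjusted p = 0.0032). Heat shock chaperone genes rose in 11 of 17 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0048, and adjusted p = 0.53 with an estimated correlation), among them Hspa1b (2.25-fold), Hsph1 (1.67-fold), Bag3 (1.55-fold) and Ahsa1 (1.35-fold). Hspa1b has the near-identical copy Hspa1a, so its reads are uncertain. In DMSO replicate 2 the heat shock list lay below the mean of DMSO replicates 1 and 3 by a median log2 difference of -0.10, with 2 of 17 members higher, and without that library 11 rose and 1 fell. Chaperones of the unfolded protein response rose in 14 of 24 cases, with Hyou1 at 1.40-fold and Dnajb11 at 1.42-fold, and 2 fell, both counts also adjusted over the list alone (camera adjusted p = 0.0082, and adjusted p = 0.53 with an estimated correlation). The 2 that fell were Herpud1, a component of protein degradation at the endoplasmic reticulum, at 0.468 of its DMSO level, and the sensor gene Atf6, from 3793 ± 196 to 2651 ± 72.7 normalised reads (SD, n = 3). In DMSO replicate 2 this list lay lower by a median of -0.04, with 7 of 24 members higher, and without that library 14 rose and 3 fell. Cholesterol synthesis genes rose in 13 of 24 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0098, and adjusted p = 0.67 with an estimated correlation), with Nsdhl at 1.77-fold, Hsd17b7 at 1.75-fold, Cyp51 at 1.74-fold and Dhcr7 at 1.38-fold. The median for this list in DMSO replicate 2 was -0.06, with 4 of 24 members higher, and without that library 13 rose and 1 fell.

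**Figure D3:**
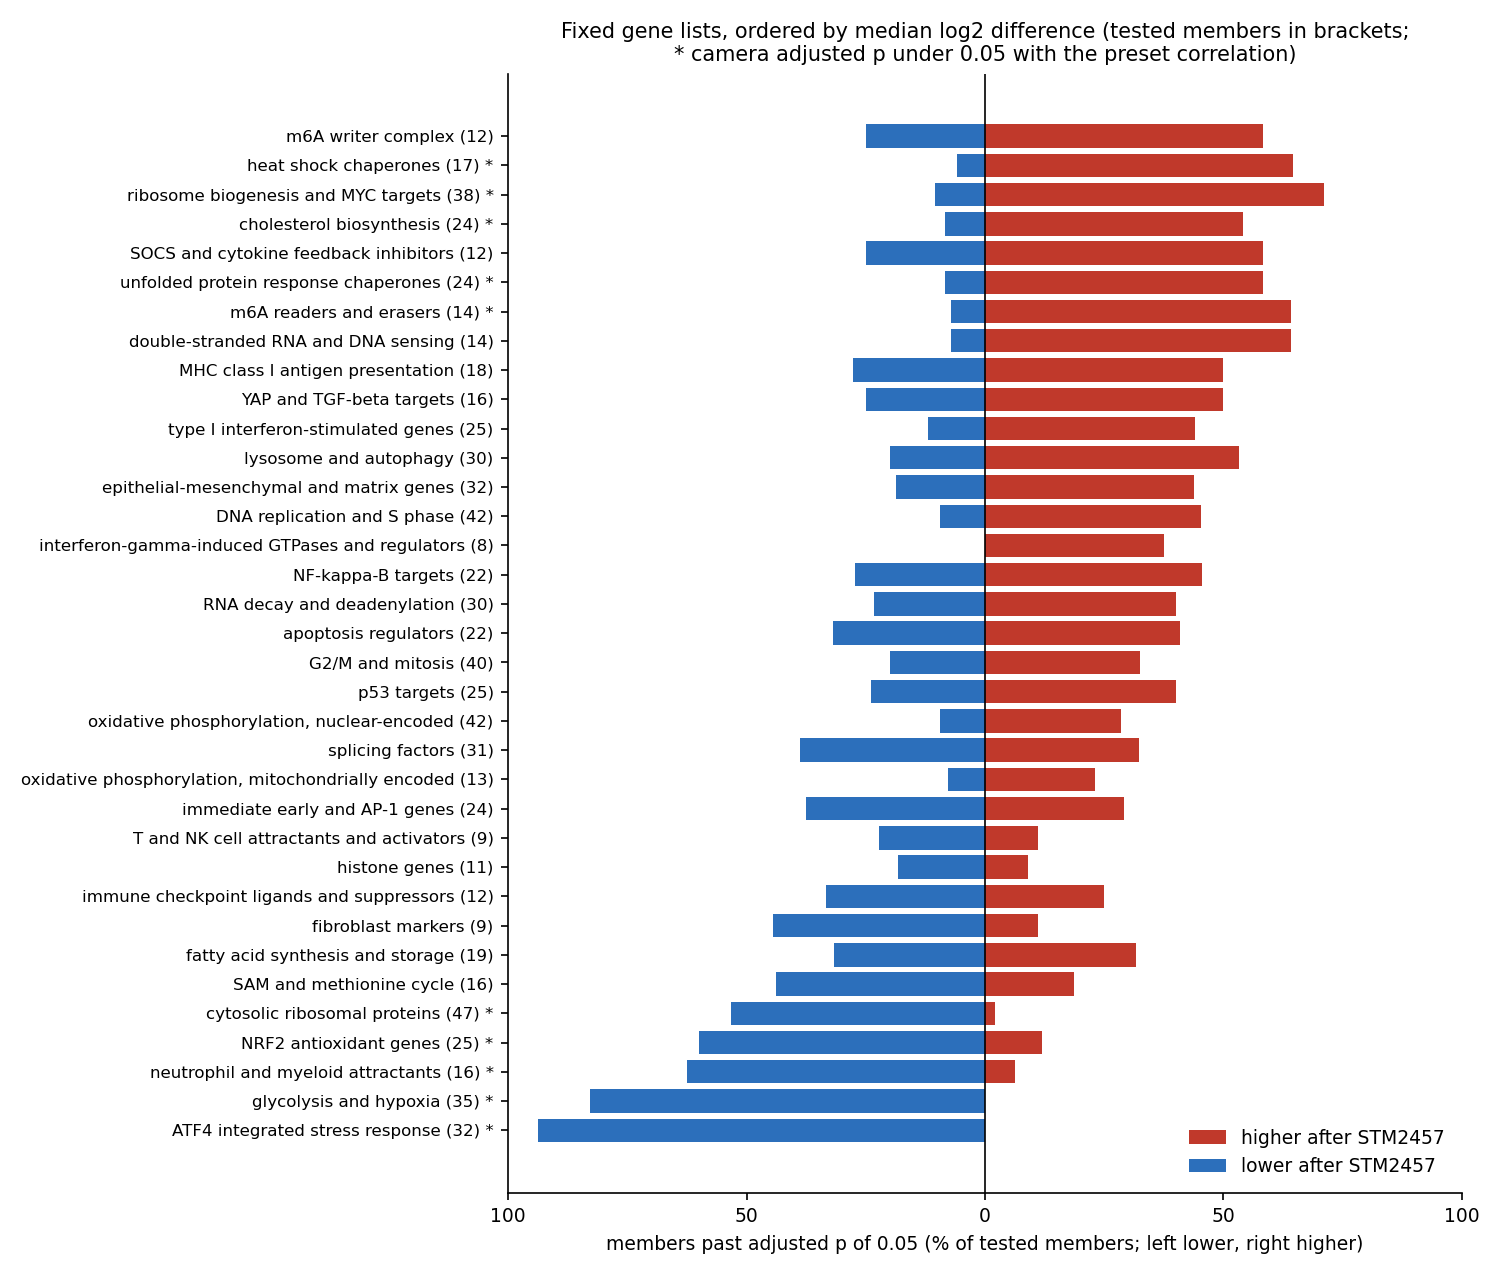
Share of tested members (x axis, in % of the tested members) that were higher (red, to the right) or lower (blue, to the left) after STM2457 in each of the 35 gene lists with at least 5 tested members (y axis, number tested in brackets), ordered by median log2 difference, with a star for camera adjusted p under 0.05 at the preset correlation. The ATF4 list (30 of 32 lower) and the glycolysis and hypoxia list (29 of 35 lower) lie at the bottom, and none of the 10 starred lists passed with an estimated correlation.

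The list of the m6A writer complex also holds the genes of separate methyltransferases, Mettl16, Mettl5, Zcchc4 and Pcif1. Of its 12 members 7 rose and 3 fell, also adjusted over the list alone. The list did not pass camera (adjusted p = 0.073, and adjusted p = 0.53 with an estimated correlation). It passed with upper-quartile centring (0.027), without a filter on low values (0.0061) and without DMSO replicate 2 (0.041). The adaptor gene Rbm15 rose from 241 ± 32.1 to 493 ± 17.6 normalised reads (SD, n = 3, limma adjusted p = 9.1e-11). Virma and Mettl16 each rose 1.49-fold, Cbll1 1.54-fold, Rbm15b 1.44-fold, Wtap 1.38-fold and Zc3h13 1.19-fold, and Pcif1, which methylates cap-adjacent adenosines, fell to 0.833. Mettl5 did not pass the test (adjusted p = 0.85). The calls of Mettl14 (0.901 of DMSO, limma adjusted p = 0.037) and Zcchc4 (0.898, adjusted p = 0.015) were lost in several alternatives, up to adjusted p = 0.13 for Mettl14 without STM2457 replicate 3 and 0.084 for Zcchc4 without STM2457 replicate 1. Mettl3 passed only with upper-quartile centring (log2 difference -0.10, adjusted p = 0.04) and without DMSO replicate 1 (-0.11, adjusted p = 0.0089). Mettl3 lies on chromosome 14 from 52294841 to 52305128 on the minus strand, and its exons overlap Tox4 on the other strand. The exons of Mettl5, Pcif1, Rbm15b, Cbll1, Igf2bp1, Igf2bp3 and Fto also overlap a gene on the other strand. Of the m6A readers and erasers, 9 of 14 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.047, and adjusted p = 0.53 with an estimated correlation). That list's call was also lost with upper-quartile centring (adjusted p = 0.051), with the stricter level filter (0.064), and without DMSO replicate 2 (0.085) or STM2457 replicate 3 (0.052). The cytoplasmic reader genes Ythdf1 and Ythdf2 rose 1.45-fold and 1.44-fold, Igf2bp1 1.34-fold and Prrc2a 1.18-fold, and Igf2bp2 fell to 0.903 of its DMSO level (limma adjusted p = 0.0019). Igf2bp3 (log2 difference 0.13 in the deposited values), Fmr1 (0.11), Ythdc1 (0.10) and the demethylase gene Fto (0.10) also rose. The call of Ythdf3 (0.07, adjusted p = 0.016) was lost with upper-quartile centring (0.23), and without DMSO replicate 1 (0.071) or STM2457 replicate 2 (0.11) or 3 (0.053). Ythdc2 (adjusted p = 0.13), Hnrnpc (0.79), Hnrnpa2b1 (0.93) and the demethylase gene Alkbh5 (0.21) did not pass, and Alkbh5 was lower with upper-quartile centring (0.0084) and without DMSO replicate 2 (0.0099).

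Genes for attractants of neutrophils and other myeloid cells were lower, 10 of 16 with 1 higher, also adjusted over the list alone (camera adjusted p = 2.4e-04, and adjusted p = 0.53 with an estimated correlation). Among the 10 was Vegfa, which the list of glycolysis and hypoxia also holds. The neutrophil chemokine gene Cxcl1 fell from 3491 ± 776 to 1294 ± 34.9 normalised reads (limma adjusted p = 0.0041) and Cxcl5 from 176 ± 59.6 to 41.7 ± 2.05 (adjusted p = 0.0081; SD, n = 3). The prostaglandin synthase gene Ptgs2 fell to 0.645, the cytokine gene Lif to 0.567 and Il34 to 0.603 of the DMSO level. Ccl20 measured 242 ± 113 normalised reads in DMSO and 58.9 ± 7.76 after STM2457 (SD, n = 3, limma adjusted p = 0.034). That call was lost without DMSO replicate 3 (0.086) or STM2457 replicate 1 (0.09), 2 (0.1) or 3 (0.1). It was also lost without a filter on low values (0.066) and with the replicate number as a block (0.087). These chemokines were highest in DMSO replicate 2, with 147, 370 and 210 reads of Ccl20 and 2805, 4367 and 3313 reads of Cxcl1 in DMSO replicates 1 to 3. Without that library 10 members fell. Cxcl1 and Cxcl5 lie on chromosome 5, from 90891241 to 90893115 and from 90759360 to 90761624.

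Of 25 type I interferon-stimulated genes tested, 11 rose and 3 fell, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.35). Ifitm3 rose 1.26-fold, Ifit2 1.22-fold and Irf9 1.40-fold, and Isg20 fell to 0.646. In the list for double-stranded RNA and DNA sensing, which also holds genes for adaptors, kinases and a transcription factor, 9 of 14 members rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.097, but 0.036 without a filter on low values and 0.038 over members not shared with another list), with the adaptor genes Sting1 at 1.26-fold, Ticam1 at 1.34-fold and Traf3 at 1.25-fold and the transcription factor gene Irf3 at 1.28-fold. With an estimated correlation the list had an adjusted p = 0.53. Its 5 members whose proteins bind double-stranded RNA, chosen after their values were seen, went different ways. Tlr3 rose 1.475-fold in the recovered reads (log2 difference 0.11 in the deposited values, limma adjusted p = 0.0034). Ddx58 (adjusted p = 0.66) and Dhx58 (0.78) did not pass. The call of Eif2ak2 as higher (0.09, adjusted p = 0.015) was lost with upper-quartile centring (0.14) and without STM2457 replicate 3 (0.12), and that of Adar as lower (-0.09, adjusted p = 0.012) without STM2457 replicate 2 (0.092). Of these 5, all but Ddx58 have exons that overlap a gene on the other strand. Of the interferon-gamma-induced genes, 3 of 8 rose, also adjusted over the list alone (camera adjusted p = 0.28): Socs1 1.59-fold, Irgm1 1.52-fold and Igtp, whose call was lost in several alternatives, up to adjusted p = 0.32 with upper-quartile centring. Irf1 did not pass (log2 difference -0.08, limma adjusted p = 0.087) but was lower with upper-quartile centring (0.019) and without DMSO replicate 1 (0.028). In MHC class I presentation 9 of 18 rose and 5 fell, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.28). Among the 9 that rose were Pdia3, Calr and Canx, which the list of unfolded protein response chaperones also holds. The class I gene H2-D1 rose 1.22-fold and H2-T23 fell to 0.535, and class I genes are close copies of each other.

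Checkpoint ligand and suppressor genes went both ways, 3 of 12 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.6). Cd274, which encodes PD-L1, measured 16.3 ± 2.09 normalised reads in DMSO and 17.5 ± 3.01 after STM2457 (SD, n = 3, limma adjusted p = 0.77), so at this depth no difference was detectable. Tgfb1 rose from 819 ± 46.3 to 1312 ± 65.9 normalised reads and Tgfb3 from 158 ± 4.31 to 238 ± 29.2 (SD, n = 3), and Pvr, a ligand of the receptor TIGIT, fell to 0.713. Of 9 T and NK cell attractants and activators, 1 was called higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.61). The 1 called higher was Tnfsf9 (1.31-fold in the recovered reads, log2 difference 0.13 in the deposited values, limma adjusted p = 0.0095), whose groups overlapped. Its call was lost with upper-quartile centring (0.052), and without DMSO replicate 2 (0.059) or STM2457 replicate 1 (0.081). Il18 was called lower, at 24.0 ± 2.49 normalised reads in DMSO and 12.9 ± 4.98 after STM2457 (SD, n = 3). That call (log2 difference -0.08 in the deposited values, limma adjusted p = 0.0087) was lost without STM2457 replicate 3 (0.066). Cxcl10 fell from 38.3 ± 2.97 to 22.5 ± 4.88 normalised reads (SD, n = 3, limma adjusted p = 0.0026), and Ccl5 had 2 reads in all libraries together and was not tested. SOCS and cytokine feedback genes rose in 7 of 12 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.2), with Socs5 at 1.30-fold. Of 22 NF-kappa-B targets 10 rose and 6 fell, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.92), among them Rela and Nfkbie, higher, and Nfkbiz and Ier3, lower. The median of that list lay above 0 and its mean and camera direction below 0.

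DNA replication and S phase genes rose in 19 of 42 cases and fell in 4 (camera adjusted p = 0.094, but 0.0032 without a filter on low values, and adjusted p = 0.61 with an estimated correlation), and G2/M genes rose in 13 of 40 and fell in 8 (0.6), both also adjusted over the list alone. Of 25 p53 targets 10 rose and 6 fell, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.93), and Cdkn1a, the cell cycle inhibitor p21, fell to 0.732 of its DMSO level (limma adjusted p = 4.3e-04). Apoptosis regulators rose in 9 of 22 cases and fell in 7 (0.6), immediate early genes in 7 and 9 of 24 (0.74), YAP and TGF-beta targets in 8 and 4 of 16 (0.51), matrix and mesenchymal genes in 14 and 6 of 32 (0.28, but 0.034 over members not shared with another list, and adjusted p = 0.67 with an estimated correlation), and lysosome and autophagy genes in 16 and 6 of 30 (0.2, but 0.014 without a filter on low values, and adjusted p = 0.53 with an estimated correlation), each also adjusted over the list alone. RNA decay genes rose in 12 of 30 cases and fell in 7 (camera adjusted p = 0.6), also adjusted over the list alone, and splicing factor genes in 10 and 12 of 31 (0.66), with 11 and 13 adjusted over the list alone. Methionine cycle genes rose in 3 of 16 cases and fell in 7 (camera adjusted p = 0.2), with 3 and 8 adjusted over the list alone, and fatty acid genes in 6 and 6 of 19 (0.6), also adjusted over the list alone. Nuclear-encoded genes of oxidative phosphorylation rose in 12 of 42 cases and fell in 4 (camera adjusted p = 0.6), with 11 and 3 adjusted over the list alone, mitochondrially encoded ones in 3 and 1 of 13 (0.8), and histone genes in 1 and 2 of 11 (0.6), both also adjusted over the list alone. The median and mean differed in sign for p53 targets and splicing factors.

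Markers of other cell types were mostly too low to test. Of the leukocyte markers 3 were tested and Cd14 rose while Itgax fell. Of the endothelial markers 3 were tested and Eng rose while Egfl7 fell. Of 3 lung epithelial markers tested 0 rose or fell by limma, and 0 erythroid markers were tested. Fibroblast markers rose in 1 of 9 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.26). Cd14, Itgax, Eng and Egfl7 were named after their values were seen.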

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

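The alternatives were fixed before the data were examined, except limma-voom on the recovered reads and total-read scaling, which were chosen after seeing the data. No called gene was called in the opposite direction under any of them. Counts of higher and lower genes stayed within 1.5 times the reported ones in all, including 3592 and 3512 with total-read scaling and 3402 to 3797 and 2704 to 3152 when 1 library was left out. Genes changed at least 2-fold numbered 72 higher and 362 lower by limma-voom on the recovered reads, where folds are not shrunken, against 0 and 3. Leaving out 1 library gave 1 to 3 lower, with 1 without DMSO replicate 2, and the cause was not tested. Lists past the threshold numbered 10, 0 with an estimated correlation and 24 by fry, which asks another question. Same-numbered DMSO and STM2457 libraries deviated together with correlations of 0.050, 0.011 and 0.040, and differently numbered ones with -0.056 to 0.022. Pairing by number is neither shown nor excluded by such small correlations. The replicate block gave 3864 higher and 3226 lower genes, 0 and 3 of them at least 2-fold, and 10 lists. It ended the call of Ccl20 (adjusted p = 0.087) and of no other named gene or list, and not every library correlated best with its own number. Over the named genes and all settings, 1528 values kept direction and side of the threshold, 37 lost their call and 6 gained one. Over the lists these numbers were 472, 14 and 22.

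Changes of sign were limited to differences near 0 that did not pass limma, for genes, or camera, for lists, in either setting, and the cause was not tested. Of the lists concerned, G2/M and mitosis (adjusted p = 0.039), RNA decay and deadenylation (0.0038) and apoptosis regulators (0.01) passed fry. With upper-quartile centring, which moved the median gene to -0.03, the differences became -0.035 for Hnrnpa2b1 and -0.029 for Cd274 and Dhx58, and the list medians became -0.006 for NF-kappa-B targets, -0.020 for p53 targets, G2/M and mitosis and nuclear-encoded oxidative phosphorylation, -0.027 for mitochondrially encoded oxidative phosphorylation, -0.026 for splicing factors, and -0.016 for RNA decay and deadenylation and apoptosis regulators. Total-read scaling gave -0.005 for Hnrnpa2b1. Immediate early and AP-1 genes had a median of 0.005 without a filter on low values and 0.012 over members not shared with another list. Leaving out 1 library gave -0.013 to 0.030 for Hnrnpa2b1, -0.017 to 0.006 for Hnrnpc, -0.032 to 0.012 for Mettl5, -0.003 to 0.018 for Cd274, -0.042 to 0.012 for Ddx58, -0.009 to 0.023 for Dhx58, -0.043 to 0.007 for T and NK cell attractants and activators, -0.025 to 0.013 for immediate early and AP-1 genes, -0.008 to 0.043 for p53 targets and -0.032 to 0.003 for immune checkpoint ligands and suppressors. Not run were the planned tests on counts, their scalings and the pseudocount, because the values are log2.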

Other observations

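Of the tests here, all except the comparison of the m6A motif with its reversed form were chosen only after the result, or values that bear on it, had been seen. Long noncoding RNA as a class was lower after STM2457. Long noncoding genes took 8141 ± 100 CPM in DMSO and 6426 ± 69.6 after STM2457 (SD, n = 3), and without Neat1 7308 ± 65.8 and 6174 ± 56.6. Among genes too low to test, lincRNA changed by -35.5%, antisense RNA by -29.9% and transcripts from bidirectional promoters by -39.4%, each lower in all 3 STM2457 libraries than in any DMSO library. The loss was not particular to long noncoding RNA: all untested genes together changed by -23.6%, protein-coding ones by -19.1%, snoRNA by -23.6%, snRNA by -26.8% and processed pseudogenes by -15.0%, also without overlap, while for unprocessed pseudogenes (-14.4%) the groups overlapped. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1. Fewer genes had any read: 19211, 19195 and 19250 in DMSO replicates 1 to 3 against 18484, 18564 and 18545 after STM2457.

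Genes with few exons rose more often. Of 895 protein-coding genes with 2 to 3 exons, 53.4% rose and 15.6% fell, with a median log2 fold in reads of 0.20, while of 1371 genes with over 20 exons 27.9% rose and 31.0% fell, with a median of -0.01. Of 156 genes with 1 exon, which have no junction, 51.3% rose and 15.4% fell, with a median of 0.17, no more than with 2 to 3 exons. The difference between genes with up to 3 and those with over 20 exons in median log2 reads, against the DMSO mean, was 0.21, 0.21 and 0.17 in STM2457 replicates 1 to 3 and -0.02, 0.01 and 0.01 in DMSO replicates 1 to 3. Kti12 and Rbm15, with 1 and 2 exons in the annotated transcript used, are examples among the named genes.

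The first pattern weighed is this excess of few-exon genes, over 9688 protein-coding genes, where the Spearman correlation of exon number with the log2 fold was -0.17 across genes, which are not independent replicates. GC content and transcript length as the whole cause are argued against, since in the quintile nearest 0 the correlation was still -0.147 within GC quintiles and -0.181 within length quintiles. A candidate explanation is m6A itself, which is placed in DRACH motifs and sparsely near exon junctions, so that its loss may stabilise transcripts with long exons. The motif was compared with its reversed form in a regression with exon number, length, GC content and level. DRACH density at least 100 nt from a junction had a standardised coefficient 0.034 above that of the reversed motif (bootstrap SE over genes 0.0142). That is the direction the explanation predicts for genes of like exon number. Because exon number was itself a term, the regression cannot tell whether m6A accounts for the excess of few-exon genes. The plain correlations were almost equal, 0.171 for DRACH and 0.169 for the reversed motif among 9 features correlated, so most of the association is not specific to the motif, and no m6A was measured here.

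The second pattern is the joint fall of the ATF4, hypoxia and myeloid attractant genes. DMSO replicate 2 alone is argued against, since without it 30, 32 and 10 members of these lists fell, against 30, 29 and 10 with all libraries. Hypoxia genes already lay lower in that library (median log2 difference -0.09), so leaving it out was bound to widen the fall of most. The count of the hypoxia list is therefore no separate test. A single gradient of culture state that also separates the DMSO libraries stays open: in DMSO replicate 2 the median deviation of the hypoxia genes was -0.641 times that of the ATF4 genes, but 1 library excludes nothing. An effect of STM2457, through METTL3 or not, and a difference in cell density or medium between the treated and untreated cultures may both lie behind the fall. The design does not separate them and neither was tested.

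The third pattern is the lower noncoding signal, part of a lower signal in most classes of low genes. Depth is argued against, since the STM2457 libraries held 1.013 times the reads of the DMSO libraries. Genomic DNA in the DMSO libraries was looked at in more than 1 way, and the ways differ: olfactory and vomeronasal receptor genes, which should be silent, changed by -30.1%, nearly as much as untested noncoding genes (-31.4%), as a DNA background would predict. The amounts argue against it as the whole cause, because noncoding genes lost 132 reads per Mb of exon per library, 27.8 times the loss in receptor genes, and all reads in receptor genes in DMSO came to 16.2. That second comparison was set up after both sets of reads had been seen, receptor genes are near the floor, and a part from DNA, unspliced RNA or an effect of the treatment stays open.

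Among the 10 ways of splitting the 6 libraries into 2 groups of 3, the real split gave 3868 genes higher and 3240 lower, where the highest of the other splits gave 0, so 1 split in each case gave as many. For genes changed at least 2-fold on the deposited scale, 10 splits gave at least the 0 higher genes, and 1 split gave the 3 lower genes, with 0 in the others. The 10 lists of the real split were reached by 2 splits, itself included, and the highest other split gave 11. With 10 splits no share under 0.05 can be had. Every other split mixes DMSO and STM2457 libraries in both groups, so that a difference between treatments adds to the spread within groups. The other splits are therefore no test of chance.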
